A study of Sus scrofa with 12 samples.

How the data were processed

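Gene expression was measured in 12 ovary samples of Iberian x Meishan F2 sows killed on day 30 of pregnancy, 6 labelled as high and 6 as low prolificacy. Per the labels' protocols, the tissue was kept frozen, RNA was isolated with a RiboPure kit and biotin-labelled cRNA was hybridised to Affymetrix porcine GeneChips. The series' design text says that each sample averages the right and left ovary of the sow. Whether tissue, RNA or values were averaged is not given in the sources used here.

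The deposited values were taken as log2 expression values per probe set. Per the submitters' processing notes, the authors used GCOS, the scanner software, and GCRMA, which corrects background from probe sequence, normalizes between arrays and summarises probes. Versions and settings are not given in the sources used here. The log2 scale was read from the values themselves, which ran from 0.97 to 15.34 with a floor near 2. The table held 24123 probe sets in 12 sows with no missing value, and 0 pairs of sows were identical. GCRMA draws dim probe sets toward a common floor, so differences among them are compressed. The precision of a difference is limited by the number of sows.

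Gene symbols came from the array annotation. Of the probe sets, 10099 had 1 symbol, 198 had several and 13826 had none. An update by Entrez ID, which matched 9989 probe sets, changed 0 symbols. The 124 Affymetrix control probe sets were left out of the tests. In a block of 62 porcine control probe sets the deposited names were found displaced by 21 places against the values. Moving them back lowered the mean gap to the spike controls of the same name from 4.15 to 0.218, and raised the correlation of the RSAD2 control with the RSAD2 gene from 0.579 to 0.923. Names of gene probe sets were checked on 768 pairs of probe sets of 1 gene, whose median correlation was 0.565 as named and -0.0011 when the second name was moved by 21 places. The 3' minus 5' differences use the moved names.

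Probe sets above 4 in at least 6 of the 12 sows were tested, which left 13390, of which 6656 had 1 symbol and stood for 5079 genes. High and low prolificacy were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and Benjamini-Hochberg adjustment at 0.05. Differences are high minus low on the log2 scale. All tests are two-sided. The labels number the animals 1 to 6 in each group and name no pairs, so the groups were treated as unpaired. Relatedness of the sows was not examined. The labels give no batch.

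The 31 gene lists, with their members, were fixed before the data were examined, as were the tests, the filter and the rule for naming genes. A list score of a sow is the mean, over members measured, of the log2 value minus the gene's mean over the 12 sows, with the brightest probe set of each gene. Lists with at least 5 members measured, 24 in all, were compared with an exact permutation test over all 924 assignments, whose smallest p is 0.00216. A list that stood out alone could reach an adjusted p of no less than 0.0519. Camera with a preset correlation of 0.01 and with an estimated correlation was the competitive alternative. Array controls were compared with the same exact test over 7 measures. Correlations across sows used 100000 permutations, those between members of the interferon list 10000, and list spreads were set against 10000 random lists of matched expression.

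The genes named are, since fewer than 10 probe sets passed, the 10 with 1 symbol and the smallest p in each direction, up to 4 members of each list by smallest p, and 20 genes fixed in advance. Liver genes, on-off probe sets, genes of wide spread and those that an alternative brought past a threshold were named after their values were seen. The list of 65 liver genes was written after albumin had been noticed and before the correlations of its members were seen. Some members, among them HP, C9 and RBP4, were also on fixed lists, so their levels may have been seen.

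The steps were tested on simulated data with the real means and spreads, with 13390 probe sets and 6 sows per group. Of 100 probe sets changed by 1 on the log2 scale 71% were called, of 100 changed by 2 it was 92%, and 10 unchanged probe sets were called. All changed probe sets lay in the same simulated data, which eases the adjusted threshold for each. These shares therefore do not show the power to find a few changed genes in the real sows. Data with no change gave 0 calls. Of simulated lists, 3 of 3 with every member shifted by 1 were called and 0 of the others. Probe sets were drawn independently, without the correlation between genes of the real data, and the 3 lists were shifted together. The calls of simulated lists therefore do not show the power for real lists, whose members vary together.

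The alternatives fixed in advance were no filter or a filter at 6, quantile normalization or median centring of each array, the animal number as a block, leaving out each sow, trend and robust moderation, array weights, the luteal score, INHA included, or the first residual component as a covariate, other thresholds, exact permutation per probe set, camera, the mean of all probe sets of a gene and genes scaled to unit SD. Chosen after the data were seen were the 3' difference of actin and GAPDH as a covariate, leaving out the 2 sows of lowest correlation, leaving out the 4 sows with albumin above 6, albumin as a covariate, the luteal list without INHA and the control names as deposited. From list scores the 3' difference was regressed out without a group term, which also removes the part of a group difference that follows it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.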

Results

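Gene expression was measured in the ovaries of 12 sows of an F2 cross between the Iberian and Meishan pig breeds, on day 30 of pregnancy. The labels place 6 sows in a high and 6 in a low prolificacy group by their EBV, the estimated breeding value, and the comparison asks which ovarian transcripts differ between sows of the 2 groups. Each sow has 1 porcine Affymetrix GeneChip, whose sample is described as the average of the right and left ovary. The array reports 24123 probe sets as log2 values after GCRMA, the authors' background correction and normalization. After this normalization the arrays were alike in level, with medians from 4.81 to 4.97 and 55.5% to 56.4% of probe sets above 4. Rank correlations between sows ran from 0.973 to 0.993, with a mean of 0.986 within groups and 0.986 between them. The number of sows limits the precision: over the 13390 probe sets tested the median 95% interval of a difference reached 0.35 to either side.

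Transcripts of the corpus luteum, the progesterone-secreting body that maintains pregnancy in the pig, were among the brightest in both groups (n = 6 each throughout). Relaxin, the peptide hormone of the pregnant corpus luteum, was read by RLN2 at 15.06 ± 0.092 (SD) in high and 15.14 ± 0.059 in low prolificacy sows. STAR, which carries cholesterol into mitochondria, stood at 14.56 ± 0.28 and 14.61 ± 0.11, and CYP11A1, which cleaves its side chain, at 13.45 ± 0.46 and 13.64 ± 0.15. PTGFR, the receptor for the luteolytic prostaglandin, stood at 13.52 ± 0.32 and 13.58 ± 0.11, and HSD3B1, which makes progesterone, at 13.03 ± 0.46 and 12.97 ± 0.16. The highest value of an array lay between 15.23 and 15.34, so RLN2 and STAR stood near the top of the scale, where a difference would be compressed. The dimmer probe sets of STAR and PTGFR differed by -0.26 and -0.61, and by -0.083 and -0.346 without high 3. Transcripts of growing follicles differed more between sows of 1 group than between groups. INHA, the inhibin alpha subunit, averaged 8.53 ± 2.79 in high and 8.83 ± 1.64 in low prolificacy sows.

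**Figure D1:**
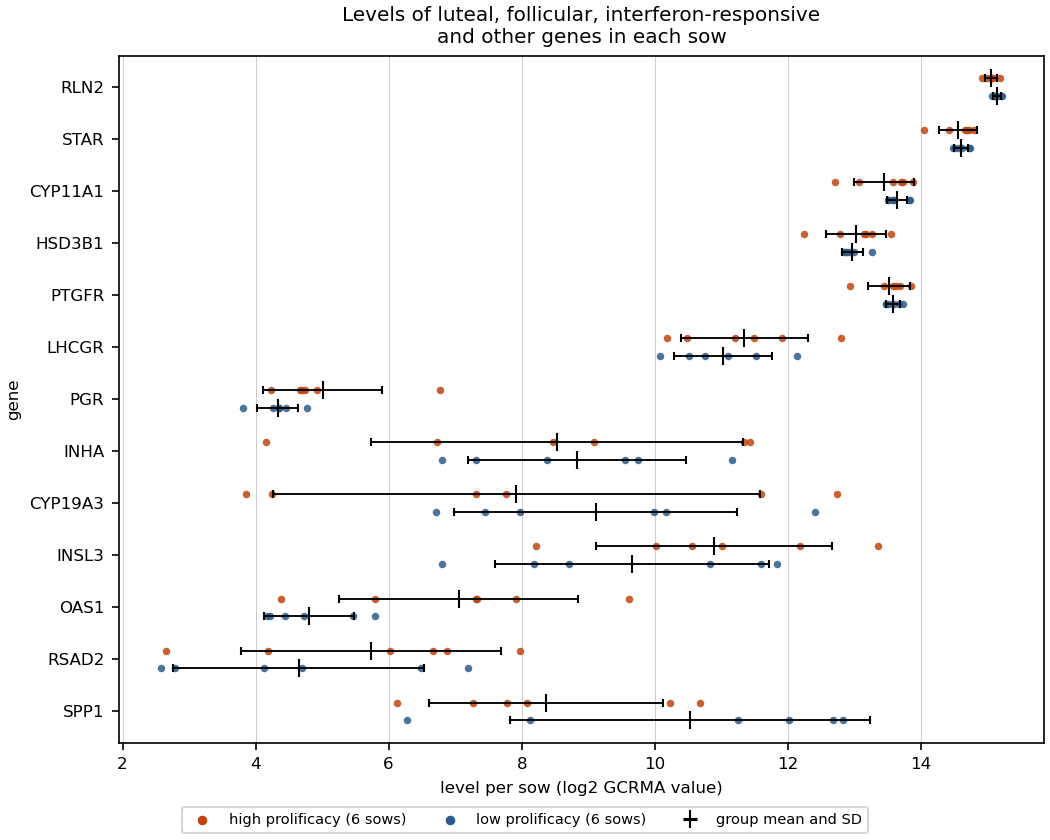
Levels of 13 genes in each sow as log2 GCRMA values on the x axis, with 1 point per sow and a bar for the group mean and SD (6 sows per group). RLN2, from 14.92 to 15.21, lay near the highest value of the arrays, 15.23 to 15.34, so its narrow range is no measure of spread, and INHA spanned 7.27 over the 12 sows.

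No gene rose or fell between high and low prolificacy at the adjusted threshold, and the leading differences are given as values only. Among transcripts higher in high prolificacy sows, FAM210B, a mitochondrial protein with a part in haem synthesis, stood at 8.67 ± 0.22 against 7.97 ± 0.25, a log2 difference of 0.70 (1.63-fold). ATP9A, a phospholipid flippase of endosomes, differed by 1.12 and 1.03 in a pair of probe sets, and CREM, a transcription factor of the cAMP pathway, by 0.72 (0.48 with the 3' difference of the control transcripts, a sign of RNA integrity, as a covariate). Among transcripts lower in high prolificacy sows, ASAH1, the lysosomal acid ceramidase, stood at 7.78 ± 0.29 against 8.91 ± 0.48, a difference of -1.12 (2.18-fold). The related lysosomal amidase NAAA differed by -0.81, the kinetochore protein ZWILCH by -1.21 and the autophagy protein ATG12 by -0.50. TTC38 had the widest gap of the leading genes, 5.07 ± 1.02 against 7.77 ± 1.48, a difference of -2.70 (6.49-fold). Its value in high 6 was 3.63, under the level of 4 used for measured probe sets.

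With limma and Benjamini-Hochberg adjustment, 0 of 13390 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.46. At an unadjusted p under 0.05 there were 755 probe sets, where 669.5 were expected if none differed. At an unadjusted p under 0.01 there were 174, where 133.9 were expected, 51 of them higher and 123 lower in high prolificacy sows. Limma with trend and robust moderation and limma with array weights also gave 0. Exact permutation of each probe set decides nothing here, since its smallest p is 0.00216 and 580 probe sets would have to reach it before any passed. The values of the 2 groups did not overlap in 63 probe sets, where chance gives 29.0 (0.216%) on average. How far that count varies over other splits of the sows was not computed, so chance is not excluded for it. A difference of 2-fold or more was seen in 84 probe sets, and 21 of these had an unadjusted p under 0.01. The limma adjusted p was 0.527 for FAM210B, ATP9A, ASAH1 and ZWILCH, 0.642 for NAAA, ATG12 and TTC38, and 0.752 for CREM. Without low prolificacy sow 1, 1 probe set with no gene symbol passed, with a difference of -1.31 and a limma adjusted p of 0.0454. With all sows its difference was -1.14, so leaving out that sow widened it.

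In every one of the 20 probe sets with a gene symbol and the smallest p in each direction, all 6 high sows lay beyond the low group's mean. The choice by p in these same sows largely fixes this, so it is no sign of consistency. GRK3, a kinase of G protein-coupled receptors, was higher by 0.58, the membrane protein TSPAN9 by 0.49 and TXLNG by 0.65. FAM162B was higher by 0.79, the junctional adhesion molecule JAM3 by 0.39 and GSE1 by 0.58. RTN3, which shapes the endoplasmic reticulum, was lower in a pair of probe sets, with differences of -0.74 and -0.64. WDR70 differed by -0.50, LOC100157002 by -0.54 and PPIP5K2, an inositol pyrophosphate kinase, by -0.53. In the high group WDR70 averaged 3.86, under the level of 4 used for measured probe sets, where differences are compressed. Their limma adjusted p values ran from 0.527 to 0.752. TXLNG differed by 0.395 and LOC100157002 by -0.36 with the 3' difference as a covariate. Other probe sets of the same genes did not always follow. FAM210B gave 0.27 and 0.30 in its other probe sets, ATP9A 0.36 and -0.14, TXLNG 0.52 and -0.011, FAM162B 0.73, CREM 0.46, 0.44 and -0.026, RTN3 -0.34, ATG12 -0.25 and WDR70 0.014.

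**Figure D2:**
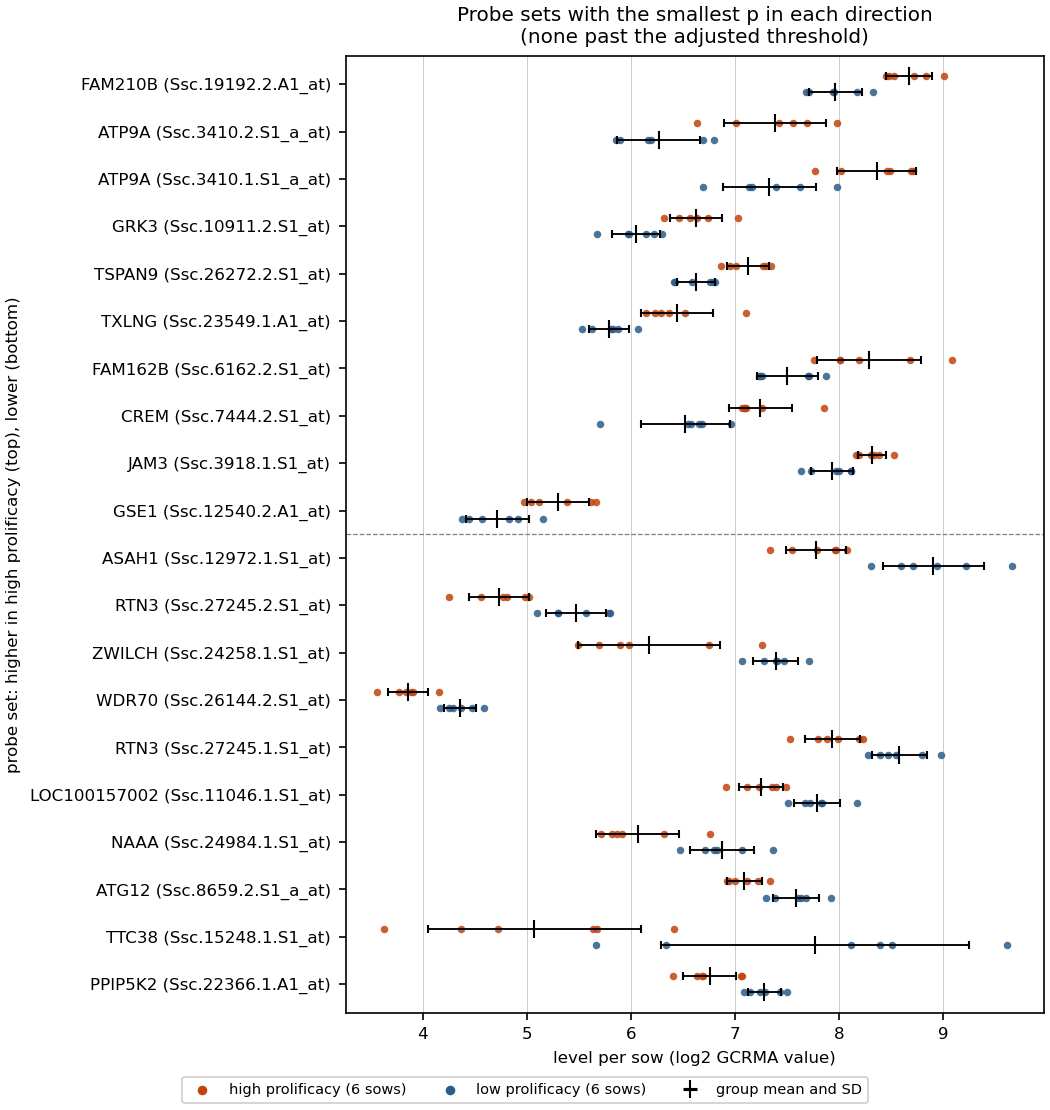
Levels of the 20 leading probe sets in each sow as log2 GCRMA values on the x axis, with 1 point per sow and a bar for the group mean and SD (6 sows per group). The 10 above the dashed line were higher and the 10 below it lower in high prolificacy sows, and none passed the adjusted threshold.

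Genes fixed in advance for their part in ovarian function or litter size gave no probe set past the limma adjusted threshold. The progesterone receptor PGR stood at 5.01 ± 0.90 in high and 4.33 ± 0.31 in low prolificacy sows, a difference of 0.68 (adjusted p = 0.888). It was 0.32 without high 5, which stood at 6.77, and 0.38 without the 4 sows with high albumin. The oestrogen receptor ESR1 differed by 0.22, and by 0.038 without high 3, 0.054 with albumin as a covariate and 0.49 with the 3' difference as a covariate. Osteopontin, SPP1, a secreted phosphoprotein of macrophages and bone also reported for litter size in pigs, stood at 8.36 ± 1.76 against 10.53 ± 2.70, a difference of -2.17 (adjusted p = 0.888). The SPP1 difference was -0.61 without the 4 sows with high albumin and -0.75 with the 3' difference of the control transcripts as a covariate. STAR differed by -0.052 and -0.26 in its 2 probe sets, CYP11A1 by -0.20, HSD3B1 by 0.060 and 0.28, and PTGFR by -0.057 and -0.61. Without high 3 CYP11A1 differed by -0.0523, the dimmer STAR probe set by -0.083 and the dimmer PTGFR probe set by -0.346. The HSD3B1 probe sets then differed by 0.217 and 0.51. The luteinizing hormone receptor LHCGR differed by 0.33 and 0.23, and INHA by -0.29. The oocyte growth factor GDF9 differed by 0.14, the cumulus matrix gene PTX3 by 0.36 and 0.088, and the angiogenic factor VEGFA by -0.14, 0.18 and -0.39. For STAR, HSD3B1, LHCGR, PTGFR, INHA, GDF9, PTX3 and VEGFA the sign of at least 1 probe set turned when a sow was left out or with another setting.

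Other genes of that group did not reach 4 in at least 6 sows and were not tested. The prolactin receptor PRLR averaged 1.86 ± 0.069 in high and 1.95 ± 0.22 in low prolificacy sows, CYP17A1, the androgen-making enzyme of theca cells, 3.28 ± 1.18 and 2.85 ± 0.73, and the follicle-stimulating hormone receptor FSHR 3.73 ± 0.82 and 3.87 ± 0.42. The 4 probe sets of CYP19A1 averaged from 1.64 to 2.69, and the oocyte factor BMP15 lay under 4 in both groups. Aromatase was also read under the symbol CYP19A3, whose brighter probe set ran from 3.86 in high 2 to 12.74 in high 1. The retinol carrier RBP4 averaged 2.497 ± 0.42 in high and 4.01 ± 2.45 in low prolificacy sows in its brighter probe set, with 6.84 in low 1 and 7.44 in low 4, and 2.94 ± 0.40 in high and 3.01 ± 0.81 in low prolificacy sows in the other. RLN and VIPR1 were not analysed here, since no probe set used here carried exactly those symbols.

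Of 31 gene lists, 24 had at least 5 measured members, and in an exact permutation test of the list scores none passed the adjusted threshold of 0.05. A list that stood out alone could not have passed, as 2 would have to reach the smallest exact p. In these lists 0 member genes passed adjusted over all genes tested in limma, and 0 passed adjusted over the list alone. With 1 sow left out, 21 of the 24 lists and 56 of the 99 probe sets named turned in sign or moved by more than 1.5 times, so that many differences below rest on few sows. Steroid and gonadotrophin receptors had the smallest exact p. Their score difference was 0.26, with 5 of 6 measured members higher in high prolificacy sows (exact p = 0.0411, adjusted p = 0.948). The difference was 0.057 with no filter on dim probe sets and 0.14 without high 2 and high 3. Beside PGR and ESR1, the glucocorticoid receptor NR3C1 differed by 0.19 and the growth factor receptor IGF1R by 0.16. Hormonal and luteal lists lay nearer to 0. Luteal steroidogenesis differed by -0.053 (exact p = 0.431, 10 of 15 members lower), with FDXR at 0.14. Without its follicular member INHA that list differed by -0.036 (exact p = 0.703). Luteal pregnancy peptides and regulators differed by 0.078 (exact p = 0.506), with the progesterone-binding membrane protein PGRMC1 at -0.24.

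Interferon-responsive genes, which defend cells against viruses, were higher in high prolificacy sows in 16 of 17 measured members, without passing. OAS1, a sensor of viral RNA, stood at 7.06 ± 1.80 against 4.80 ± 0.68, a difference of 2.25 (4.77-fold). GBP1 differed by 0.76, IFIT2 by 0.48 and IRF7, a transcription factor of the interferon response, by 0.27. The score difference was 0.61, with an exact p of 0.158 and an adjusted p of 0.948. It was 0.32 with the 3' difference of the control transcripts regressed out, in a fit without a group term. As the 3' difference was itself larger in the high group, that fit also takes out part of a group difference. Within groups the score followed the 3' difference little, at r = 0.057 in the high and 0.133 in the low group. Scores ran from -0.84 to 1.17 in the high and from -0.93 to 0.61 in the low group. Camera with a preset correlation gave an adjusted p of 3.86e-07, and with an estimated correlation, 0.567 for this list, the adjusted p was 0.714. The limma adjusted p of OAS1 was 0.752. Adjusted over the list alone, OAS1 and GBP1 passed without high prolificacy sow 3, without sows 2 and 3 of that group and with array weights. OAS1 alone also passed so with the luteal score or albumin as a covariate. High 3 held the lowest OAS1 and GBP1 of its group, 4.38 and 5.46. Leaving it out therefore widens both differences, and those passes are no added support.

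Immediate early and heat shock genes, which respond to stress of cells, were higher in high prolificacy sows in 16 of 20 members. ZFP36 differed by 0.70, the co-chaperone BAG3 by 0.80, NR4A2 by 0.88 and DUSP1 by 0.36. Without high 2, which stood at 7.99, NR4A2 differed by 0.38, and ZFP36 differed by 0.27 without high 2 and high 3. BAG3 differed by 0.29, DUSP1 by 0.12 and NR4A2 by -0.17 with the 3' difference as a covariate. The score difference of 0.31 had an exact p of 0.136 (adjusted p = 0.948). Camera with a preset correlation gave an adjusted p of 0.00216, and the adjusted p was 0.714 with an estimated correlation. The difference was 0.068 without high prolificacy sows 2 and 3, the 2 arrays of lowest correlation with the others. It was 0.13 with the 3' difference of the control transcripts regressed out, again without a group term. That 3' difference was larger in the high group for actin, at 2.59 ± 0.45 against 2.12 ± 0.13 (exact p = 0.0325, adjusted p = 0.0758).

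Genes of the mitochondrial respiratory chain were lower in high prolificacy sows in 21 of 27 members, by a small amount that did not pass. The score difference was -0.064 (exact p = 0.301), with the complex I subunits NDUFA9 at -0.30, NDUFA5 at -0.27 and NDUFA8 at -0.11 and the complex III subunit UQCRB at -0.11. That score difference was -0.123 without the 4 sows with high albumin. Oxidative stress and detoxification genes were lower in 18 of 26 members, with a score difference of -0.080 (exact p = 0.0931). It was -0.044 with the 3' difference regressed out, without a group term, and -0.14 without the 4 sows with high albumin. The glutathione transferases GSTO1 and GSTA1 stood at 11.13 ± 0.49 against 11.78 ± 0.098 and at 14.38 ± 0.11 against 14.69 ± 0.18, differences of -0.65 and -0.31. The peroxidase PRDX1 differed by -0.19, and GCLM, of glutathione synthesis, by 0.62. GSTO1 passed adjusted over the list alone without high prolificacy sow 4 and with the first residual component or the 3' difference as a covariate. High 4 held the highest GSTO1 of its group, 11.64, so leaving it out widens the difference. The first residual component comes from these same sows with the group means removed. It left the difference at -0.65 and lowered the residual spread, so neither pass is added support. Hypoxia and glycolysis genes differed by -0.034 (exact p = 0.530), with PFKP at 0.31 and LDHA at -0.32.

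Lists of growing follicles and cell division had a wide spread within groups. Granulosa and growing follicle genes differed by -0.16 (exact p = 0.745), with group SDs of 0.91 and 0.50, and FOXO1 at 0.59 and IGFBP5 at -0.45. Proliferation genes differed by 0.074 (exact p = 0.903), with SDs of 1.12 and 0.70, and RRM1 at 0.26, CDC20 at 0.59, MCM2 at -0.30 and PCNA at -0.12. Without high 3, which stood at 8.57, CDC20 differed by 0.069, and with the 3' difference as a covariate MCM2 and PCNA differed by 0.92 and 0.32. Cholesterol synthesis and uptake genes differed by -0.014 (exact p = 0.970), with SC5D at -0.26 and INSIG1 at 0.59. Without high 3 SC5D differed by -0.0063 and INSIG1 by 1.10, and without high 2 INSIG1 differed by 0.18. With the 3' difference regressed out of the scores, without a group term, the differences were 0.33 for granulosa, 0.64 for proliferation and -0.41 for cholesterol genes, and none passed. Genes of TGF beta superfamily signalling, to which the ovarian growth factors belong, differed by 0.027 (exact p = 0.775), with the receptors ACVR1 at 0.23 and BMPR1A at -0.13. Ovulation and cumulus matrix genes differed by 0.14 (exact p = 0.615), with the collagen crosslinker LOX at 0.52. Apoptosis and luteolysis genes differed by -0.012 (exact p = 0.868), with MCL1 at 0.22, TNFRSF1A at 0.17, CLU at -0.23 and CDKN1A at -0.21. The insulin-like growth factor system differed by 0.028 (exact p = 0.894), with IGFBP6 at 0.59, STC1 at 0.58, IGF1 at -0.21 and its binding protein IGFBP2 at -0.53, which passed adjusted over the list alone with albumin as a covariate (-0.79). IGF1 differed by -0.042 and IGFBP2 by -0.24 with the 3' difference as a covariate, and IGFBP6 by 1.2 without the 4 sows with high albumin.

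Lists of other cell types and of immune function did not pass either. Stroma and extracellular matrix genes differed by 0.045 (exact p = 0.781), although 17 of 21 members were higher in high prolificacy sows. The list differed by 0.255 without the 4 sows with high albumin. The protease inhibitor TIMP3 at -0.55 and fibronectin, FN1, at -0.69 lay on the other side, and TIMP3 passed adjusted over the list alone without low prolificacy sow 1. Low 1 held the lowest TIMP3 of its group, 4.29, so leaving it out widens that difference. Smooth muscle and pericyte genes differed by 0.033 (exact p = 0.870), with PDGFRB at 0.25, endothelium and angiogenesis genes by 0.0072 (exact p = 0.963), with CLDN5 at -0.28, and adipose tissue genes by -0.0096 (exact p = 0.959), with PPARG at 0.53. Macrophage and myeloid genes differed by -0.093 (exact p = 0.714), with LAPTM5 at -0.33 beside SPP1 and, on the other side, FCGR2B at 0.38 and CD163 at 0.53. LAPTM5 differed by -0.10 and CD163 by 0.048 with the 3' difference as a covariate, and CD163 differed by 0.27 without high 5 and FCGR2B by 0.16 without low 6. MHC class I and II genes were higher in 13 of 16 members, with a difference of 0.10 (exact p = 0.517) and the proteasome subunit PSMB8 at 0.33. Without high 5 the list differed by 0.0089 and PSMB8 by 0.14, and without high 2 and high 3 the list differed by 0.305. Complement and coagulation genes differed by 0.028 (exact p = 0.853), with CD55 and CD59, which shield cells from complement, at 0.84 and 0.29, C7 at 0.495 and PLAT at -0.44 (0.050 without high 2 and high 3). Acute phase and inflammation genes differed by 0.045 (exact p = 0.805), with the chemokine CXCL2 at 0.78 and haptoglobin, HP, at -1.31. CXCL2 differed by 0.24 and CD55 by 0.42 with the 3' difference as a covariate. Litter size candidates reported in pigs differed by -0.087 (exact p = 0.442), with STAT5A at 0.21 beside PGR, SPP1 and IGFBP2.

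In several lists the mean, the median member and the camera test differed in sign. The median member was 0.032 for the litter size candidates and the camera direction was up, against a mean of -0.087. It was -0.0040 for luteal pregnancy peptides and -0.089 for complement, against positive means and an upward camera direction. For the macrophage, granulosa and apoptosis lists the mean and median were negative and camera pointed up, and for the insulin-like growth factor system both were positive and camera pointed down. Lists with fewer than 5 measured members were not tested. They were theca and androgen synthesis, oocyte, and B cell and plasma cell (3 members each), red blood cell (3), nerve and glia (4), oviduct and surface epithelium (2) and T and NK lymphocyte (1).

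**Figure D3:**
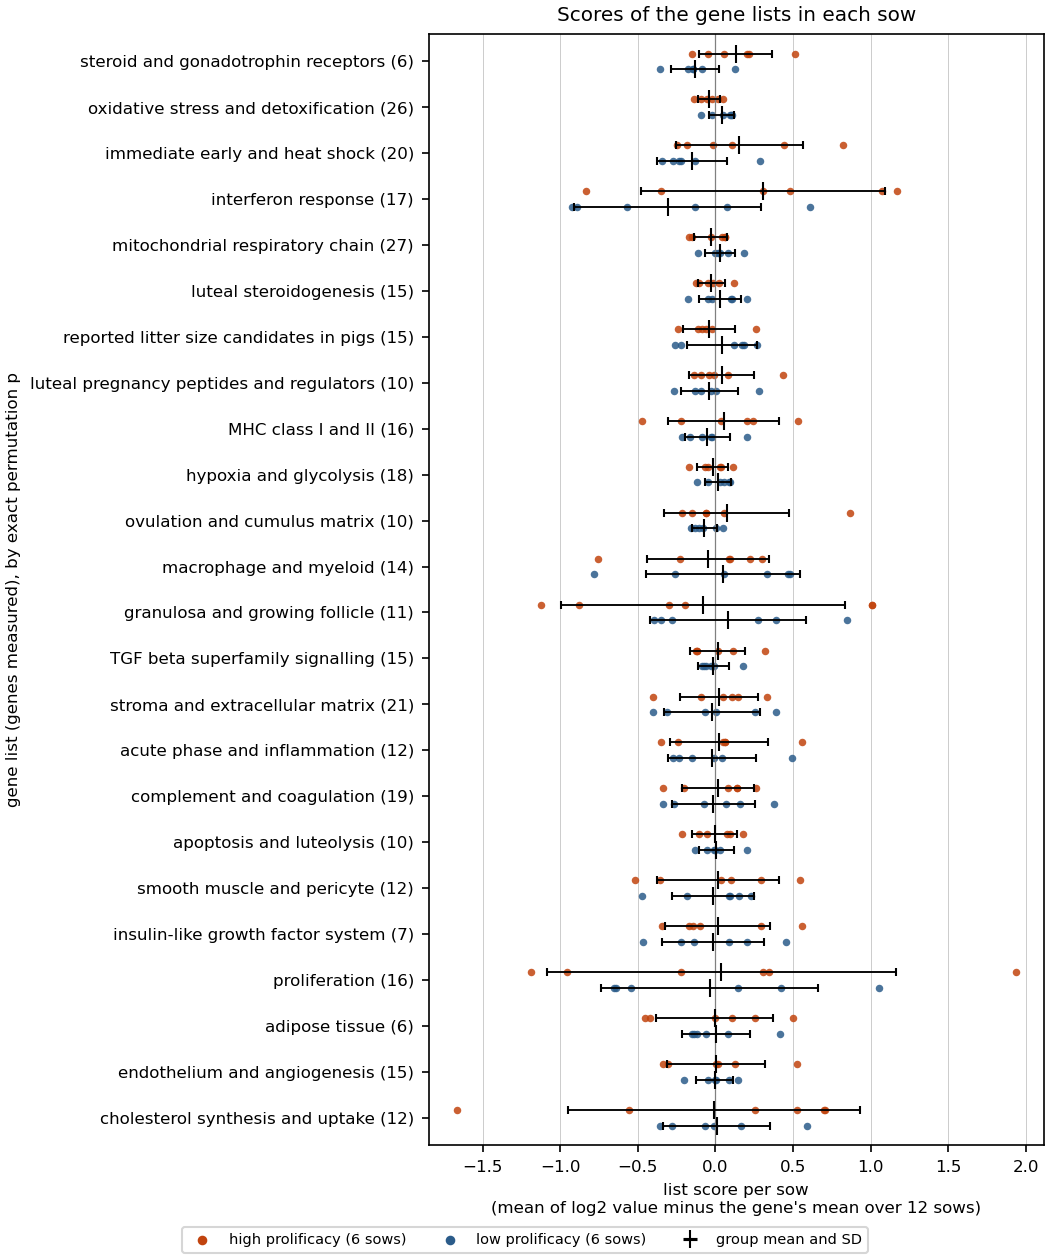
Scores of the 24 gene lists in each sow on the x axis (mean log2 value minus the gene's mean over the 12 sows), with 1 point per sow and a bar for the group mean and SD (6 sows per group). Granulosa scores ran from -1.13 to 1.01 and proliferation scores from -1.19 to 1.93, with both groups on either side of 0.

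Transcripts made mainly by the liver were bright in some ovary samples. Albumin, ALB, stood at 12.61 in low prolificacy sow 1, 12.40 in low 4, 8.80 in low 3 and 8.67 in high 5, and between 2.04 and 3.33 in the other 8 sows. The fibrinogen chain FGB stood at 11.52 in low 1 and 12.87 in low 4, the apolipoprotein APOC3 at 10.89 and 11.42, transferrin, TF, at 11.05 and 9.96, and the alcohol-oxidizing enzyme CYP2E1 at 8.94 and 9.21. Of 68 other probe sets of a written liver list, 35 lay at or under 4 in the median sow and above 4 in at least 1. Of these 31 (88.6%) had their 2 highest levels in low 1 and low 4, where chance gives 1.52% for a given pair of sows. Of 22 that lay at or under 4 in every sow 5 did, and 11 lay above 4 in the median sow. The mean liver marker level was 2.60 ± 0.21 in high and 4.15 ± 2.19 in low prolificacy sows (exact p = 0.121), and albumin had an exact p of 0.152. Of the fixed lists, those of complement, acute phase and litter size candidates hold genes that the liver also makes, among them HP, C9 and RBP4. HP stood at 12.96 in low 4 and 11.70 in low 1, and at 12.26 in low 5, 12.17 in high 2 and 12.08 in low 2, where albumin stayed under 4. HP passed adjusted over its list alone without high 2, the highest of its group, and leaving that sow out widens the difference. FN1, also made by the liver, differed by -0.44 without the 4 sows with high albumin. Without these 4 sows 0 probe sets passed in limma.

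**Figure D4:**
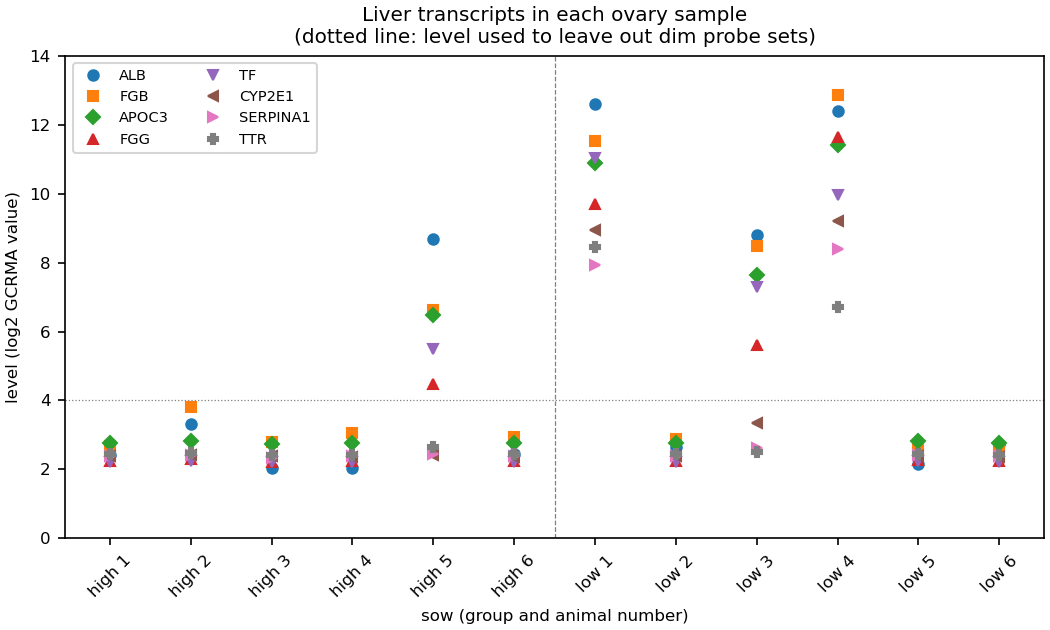
Levels of 8 liver transcripts in each of the 12 ovary samples as log2 GCRMA values on the y axis, with 1 marker per transcript and the dashed line between high and low prolificacy sows. All 8 lay above 4, the dotted line, in low 1 and low 4, and ALB reached 12.61 and 12.40 there.

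Array controls differed a little between the groups. Hybridisation spikes averaged 10.62 ± 0.12 in high and 10.43 ± 0.11 in low prolificacy sows (exact p = 0.0238, n = 6 each). The difference between 3' and 5' probe sets was 2.02 ± 0.20 against 1.77 ± 0.11 for GAPDH (exact p = 0.0195) and 0.54 ± 0.23 against 0.43 ± 0.065 for EF1A (exact p = 0.301). Over the 7 measures the adjusted p was 0.0758 for the spikes, actin and GAPDH, so none passed. With median centring of the arrays the spikes passed (exact adjusted p = 0.026), and without high prolificacy sow 3 actin and GAPDH did (exact adjusted p = 0.0303 and 0.0455). PolyA spikes (exact p = 0.846), the array median (exact p = 0.519) and the percent of probe sets above 4 (exact p = 0.892) were closer. Normalization between arrays draws the median and that percent together, so they say little of a technical difference. With the 3' difference of actin and GAPDH as a covariate INHA differed by 1.93 in place of -0.29, and 5 genes passed adjusted over their list alone, VEGFB, C9, PFKP, GPX3 and GSTO1. That fit takes 1 slope for both groups, though the actin SD was 0.45 in the high and 0.13 in the low group. The granulosa score followed the 3' difference at r = -0.835 within the high and 0.564 within the low group. The values with this covariate therefore lean on the high sows and decide nothing on the group. The first principal component held 32.8% of the variance and did not separate the groups (exact p = 0.857), and the second held 14.9% (exact p = 0.0346, not adjusted).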

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

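The comparison of single sows with their group was chosen in advance, and no test in this part was chosen after a result was seen. A sow stood apart where its gap to the nearest other sow, divided by the range of its group of 6, passed Dixon's 95% critical value. That happened in 14 of 260 groups (5.38%), where chance gives about 1 in 20, so a sow standing apart is not by itself unusual here. No explanation, technical or biological, was tested for these single values.

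In high prolificacy sow 3 the cell division gene CDC20 stood at 8.57, where the next sow of the group stood at 5.88. The same sow held the highest ESR1 of its group, 5.57 against 4.69 in the next. Its UQCRB, a subunit of complex III, was the lowest of the group at 10.99, against 11.35. In high prolificacy sow 5 the progesterone receptor PGR stood at 6.77, against 4.93 in the next. The immunoproteasome subunit PSMB8 stood at 7.26 there, against 6.37, and the score of the ovulation and cumulus matrix list at 0.87, against 0.052. In high prolificacy sow 2 the nuclear receptor NR4A2 stood at 7.99, against 5.37, and CREM at 7.85, against 7.26. CREM also set low prolificacy sow 3 apart, at 5.70 against 6.55. The immediate early and heat shock score of low 3 was the highest of its group, 0.28 against -0.13. NDUFA8, of complex I, stood at 10.05 in high 4, against 9.83. HSD3B1, in its brighter probe set, stood at 13.27 in low 5, the highest of its group. TNFRSF1A, a receptor for tumour necrosis factor, stood at 7.996 in low 6, against 8.39. The score of the TGF beta superfamily signalling list was 0.18 in low 2, against -0.011.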

How the results depend on the processing

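Settings chosen after the data were seen are the 3' difference of actin and GAPDH, the sets without 2 or 4 sows, albumin as a covariate, the luteal list without INHA and the control names as deposited, and the others were chosen before. The count of 0 probe sets past the adjusted threshold stayed at 0 in every limma setting tried except without low prolificacy sow 1, so its range over single sows left out was 0 to 1. At an unadjusted p under 0.01 it was 174. Exact permutation per probe set decides nothing, since 580 would have to reach its smallest p. The count of 0 lists past stayed at 0 except in camera with a preset correlation, where 2 passed, interferon response (1.60, adjusted p = 3.86e-07) and immediate early and heat shock (0.97, adjusted p = 0.00216), and neither did with an estimated correlation. Of exact tests, 2 lists would have to reach the smallest p with all sows or 1 left out, 3 without the 2 least correlated sows, 9 without the 4 sows with high albumin and 16 with the block, so the last pair say little on stability. Of 99 named probe sets 76 kept 1 sign in every setting, and of 24 lists 7 did. With 1 sow left out, 56 of the probe sets and 21 of the lists turned or moved by more than 1.5 times. No named probe set passed over all genes, with a smallest adjusted p of 0.140, and no list in a permutation test, with a smallest of 0.416. Where a sign turned or a count moved, the cause was not tested. Signal over background limits what can be said of probe sets near the floor.

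Adjusted over the list alone, the count of genes moved from 0 to 2 with array weights (OAS1 and GBP1), 1 with the luteal score as a covariate (OAS1), 1 with the first residual component (GSTO1), 5 with the 3' difference as a covariate, 2 without the 2 least correlated sows (OAS1 and GBP1) and 2 with albumin as a covariate (OAS1 and IGFBP2). The first residual component comes from the same fit, leaves differences unchanged and lowers the residual spread, so its pass is no added support. Leaving out single sows gave 0 to 2, with HP passing without high 2 (adjusted p = 0.0487), OAS1 and GBP1 without high 3 (0.00629 and 0.0376), GSTO1 without high 4 (0.0420) and TIMP3 without low 1 (0.0461). In each of these the sow left out ran against the group difference. Leaving it out widens the difference, so these passes are no added support. Of the array controls, the count past moved from 0 to 1 with median centring, where the difference of the hybridisation spikes was 0.22, and ranged from 0 to 2 with single sows left out. The 2 were actin and GAPDH without high 3. Over the sows left out the actin difference ran from 0.34 to 0.60 and that of GAPDH from 0.18 to 0.28, and that of the spikes from 0.18 to 0.24. With the control names as deposited the differences were 0.142 for actin (exact adjusted p = 0.5758), 0.15 for GAPDH and 0.041 for EF1A, against 0.469, 0.248 and 0.11 with the names moved.

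The animal number as a replicate block gave 0 probe sets past the threshold. It also gave 0 lists and 0 array controls, where 16 lists or 5 controls would have to reach its smallest exact p of 0.0313. Deviations of sows with the same number correlated from -0.46 to 0.17, with 2 of 6 pairs above 0.1, and 1 of the 6 high prolificacy sows correlated best with its own number. The values thus give no sign that the numbers pair the sows, but 6 pairs cannot exclude a shared litter or batch.

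With no filter on dim probe sets, the list differences became -0.0756 for ovulation and cumulus matrix, -0.00852 for endothelium and angiogenesis, -0.044 for complement and coagulation, 0.0176 for apoptosis and luteolysis and -0.0323 for insulin-like growth factor system. With the filter at 6, the list differences became -0.0419 for luteal pregnancy peptides and regulators, -0.0138 for endothelium and angiogenesis and -0.0404 for acute phase and inflammation. With quantile normalization, the difference became 0.00551 for the brighter PTGFR probe set. The difference of the cholesterol synthesis and uptake list became 0.00288. With array weights, the difference became 0.0416 for the brighter STAR probe set, -0.12 for the brighter LHCGR probe set, -0.12 for the dimmer LHCGR probe set, 0.0421 for the brighter PTGFR probe set, -0.0221 for GDF9 and -0.00724 for IGF1R. With the luteal score as a covariate, the difference became 0.17 for INHA. In camera, where the value is the mean moderated t of the members minus that of the other genes, the sign was the opposite of the score difference at either correlation, with 0.09 for granulosa and growing follicle, 0.0477 for macrophage and myeloid, 0.17 for apoptosis and luteolysis, -0.0444 for insulin-like growth factor system and 0.27 for reported litter size candidates in pigs. With the mean of all probe sets of a gene, the list differences became -0.0127 for endothelium and angiogenesis and -0.0352 for insulin-like growth factor system. With genes scaled to unit SD, the list differences became -0.0245 for luteal pregnancy peptides and regulators, -0.0265 for complement and coagulation, 0.0122 for apoptosis and luteolysis, -0.098 for insulin-like growth factor system and 0.0707 for reported litter size candidates in pigs. With the 3' difference as a covariate, the difference became -0.30 for the brighter HSD3B1 probe set, -0.35 for the dimmer HSD3B1 probe set, -0.12 for the brighter LHCGR probe set, -0.15 for the dimmer LHCGR probe set, 1.93 for INHA, -0.0975 for the dimmer PTX3 probe set, -0.72 for INSIG1, 0.14 for DES, 0.17 for CLDN5, -0.00754 for VWF, 0.92 for MCM2, 0.32 for PCNA, -0.0821 for MCL1, -0.0279 for TNFRSF1A, 0.00925 for LDHA and -0.17 for NR4A2. With the 3' difference regressed out of the scores, without a group term, the list differences became 0.33 for granulosa and growing follicle, -0.0227 for TGF beta superfamily signalling, -0.0564 for endothelium and angiogenesis, 0.0196 for macrophage and myeloid, -0.0791 for acute phase and inflammation and 0.0259 for hypoxia and glycolysis. Without the 2 least correlated sows, the difference became 0.0509 for the brighter STAR probe set, -0.18 for the brighter LHCGR probe set, -0.24 for the dimmer LHCGR probe set, 0.0744 for the brighter PTGFR probe set and 0.0503 for PLAT. The list differences became 0.23 for cholesterol synthesis and uptake, -0.0496 for TGF beta superfamily signalling, -0.00389 for stroma and extracellular matrix, -0.00547 for smooth muscle and pericyte, -0.0226 for acute phase and inflammation, -0.15 for proliferation, -0.0793 for insulin-like growth factor system and 0.0751 for adipose tissue. Without the 4 sows with albumin above 6, the difference became -0.0244 for the brighter HSD3B1 probe set, -0.42 for the dimmer PTX3 probe set, 0.0523 for IGFBP5, -0.0119 for VWF and 0.095 for PCNA. The list differences became -0.0917 for luteal pregnancy peptides and regulators, -0.0177 for TGF beta superfamily signalling, -0.0246 for ovulation and cumulus matrix, -0.11 for endothelium and angiogenesis and 0.0777 for macrophage and myeloid. The difference in the array median became 0.0198. With albumin as a covariate, the difference became 0.0482 for PCNA.

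Leaving out single sows turned the sign of some results, with these lowest and highest differences: GDF9 -0.0688 to 0.26, the brighter HSD3B1 probe set -0.0438 to 0.22, INHA -0.87 to 0.58, the dimmer LHCGR probe set -0.0449 to 0.43, PCNA -0.28 to 0.0147, the brighter PTGFR probe set -0.12 to 0.0607, the dimmer PTX3 probe set -0.14 to 0.40, the brighter STAR probe set -0.10 to 0.0511 and the brightest VEGFA probe set -0.32 to 0.0617. For lists the ranges were TGF beta superfamily signalling -0.0337 to 0.0657, acute phase and inflammation -0.0624 to 0.15, adipose tissue -0.11 to 0.0799, apoptosis and luteolysis -0.0486 to 0.03, cholesterol synthesis and uptake -0.16 to 0.32, complement and coagulation -0.0376 to 0.10, endothelium and angiogenesis -0.0967 to 0.0758, granulosa and growing follicle -0.38 to 0.0476, insulin-like growth factor system -0.0805 to 0.12, luteal pregnancy peptides and regulators -0.00188 to 0.14, macrophage and myeloid -0.26 to 0.0487, ovulation and cumulus matrix -0.0171 to 0.20, proliferation -0.31 to 0.32, smooth muscle and pericyte -0.0725 to 0.14 and stroma and extracellular matrix -0.0321 to 0.13. For array controls they were the polyA spikes -0.15 to 0.0703 and the percent of probe sets above 4 -0.069 to 0.10.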

Other observations

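The tests of RNA degradation, growing follicles, macrophages, liver RNA and the prolificacy group, the count of splits with adjusted calls, the relations between scores, the spread of single genes and lists and the ratio of variances were chosen after the result was seen. The other tests in this part were chosen before. Follicular transcripts differed widely from sow to sow. The aromatase CYP19A3, of oestrogen synthesis, ran from 3.86 in high 2, under the level of 4 used for measured probe sets, to 12.74 in high 1. INHA spanned 7.27 on the log2 scale, HSD17B1, which makes oestradiol, 7.24, and INSL3, the peptide hormone of theca cells, 6.55. The cell division genes CCNB1 and TOP2A spanned 4.87 and 3.98, both highest in high 3 and lowest in high 4. Of luteal genes LHCGR spanned 2.72 and the lipoprotein receptor SCARB1 1.35, and INHA is on the luteal steroidogenesis list too. STAR and RLN2 spanned 0.76 and 0.29 near the highest value of the arrays, where differences would be compressed, so their ranges cannot be set against those of the other genes. None of these separated the groups, with exact p values from 0.0823 for RLN2 to 0.924 for CCNB1. The score of the granulosa list varied with an SD of 0.71 over the sows, more than all 10000 random lists of matched expression, whose median was 0.109. Random lists hold unrelated genes whose deviations average out. The comparison therefore shows members that vary together, not an unusual spread of the sows. The luteal steroidogenesis score, with an SD of 0.113, stood at percentile 79.9, but INHA ran against its other members (r = -0.689), and without INHA the SD was 0.1501 and the percentile 94.3.

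Genes of sterol synthesis and of the interferon response also varied widely. INSIG1, a sterol sensor, ran from 9.05 in high 3 to 13.62 in high 2, SQLE spanned 2.92 and FASN, of fatty acid synthesis, 2.56, each lowest in high 3. Among interferon-responsive genes IFIT1 spanned 3.41 and MX1 2.54, and RSAD2 and ISG15 at least 5.39 and 4.70, as their lowest values, 2.58 and 3.19, lay under 4. The highest values of RSAD2 and IFIT1 lay in high 1 and those of ISG15 and MX1 in high 5. Cholesterol, proliferation and interferon scores had SDs of 0.67, 0.89 and 0.74, each above all 10000 random lists, which again shows members that vary together.

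Of 17 relations computed across the 12 sows, the granulosa score went with the proliferation score (r = 0.802, permutation p = 0.00133, adjusted p = 0.0113; rho = 0.769, permutation p = 0.00464). Without the 2 sows farthest from the median, high 1 and high 3, r was 0.776, and it was 0.856 within the high and 0.692 within the low group. The granulosa score went against the cholesterol synthesis score (r = -0.816, permutation p = 0.00037, adjusted p = 0.00629; rho = -0.818, permutation p = 0.00213; without the 2 sows -0.764, within the high group -0.866 and within the low -0.668). It went with the smooth muscle score (r = 0.720, permutation p = 0.0090, adjusted p = 0.0306; rho = 0.692, permutation p = 0.0157; without the 2 sows 0.658, within the high group 0.805 and within the low 0.544). Its relation with the endothelium score (r = -0.675, permutation p = 0.0131, adjusted p = 0.0370; rho = -0.797, permutation p = 0.0033) was -0.419 without the 2 sows, -0.642 within the high and -0.893 within the low group. With the stroma score r was 0.630 (permutation p = 0.0299, adjusted p = 0.0727; rho = 0.741, permutation p = 0.00777; without the 2 sows 0.529, within the high group 0.870 and within the low 0.447), and with the luteal score 0.298 (permutation p = 0.344, adjusted p = 0.390; rho = 0.252, permutation p = 0.430; without the 2 sows 0.585, within the high group 0.084 and within the low 0.592). The sign of the luteal relation rests on INHA, which went with the granulosa score at 0.944. Without INHA r was -0.744 (permutation p = 0.0048, not adjusted; rho = -0.727, permutation p = 0.00993; without the 2 sows -0.521, within the high group -0.901 and within the low -0.252).

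The joint variation of granulosa, proliferation and stromal genes has a few possible sources. The granulosa score went with the 3' difference at -0.565 (permutation p = 0.0539, adjusted p = 0.102; rho = -0.315, permutation p = 0.321; without the 2 sows -0.646), at -0.835 within the high and 0.564 within the low group. RNA degradation as the whole cause is argued against, since the granulosa and proliferation scores still correlated at 0.722 with the 3' difference regressed out of both (permutation p = 0.00773, adjusted p = 0.0306; rho = 0.699, permutation p = 0.0141). The prolificacy group as the whole source is argued against too, since with the group means removed the granulosa and proliferation scores correlated at 0.8134 (p = 0.00369, permuted within groups) and the granulosa and stroma scores at 0.647 (p = 0.0179). A part played by the group stays open, with an exact p of 0.745 for the granulosa score. A differing share of growing follicles in the pieces taken may be one, as INSL3, on none of these lists, correlated with the granulosa score at 0.786 (permutation p = 0.00268, adjusted p = 0.0152; rho = 0.895, permutation p = 0.00016). That value was 0.656 without high 1 and high 3, 0.943 within the high and 0.936 within the low group, and the pattern was found and tested on the same sows.

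The joint variation of interferon-responsive genes could not be traced. The prolificacy group as the whole source is argued against, since with the group means removed the 17 members correlated at a mean of 0.5669 (p = 0.0001, the smallest that 10000 permutations within groups can give). A part played by the group stays open, with an exact p of 0.158. The interferon score correlated with the macrophage score at 0.394 (permutation p = 0.206, adjusted p = 0.292; rho = 0.462, permutation p = 0.134; without high 1 and high 5 0.283), at 0.779 within the high and 0.234 within the low group, so a share of myeloid cells stays open. With the hybridisation spikes r was 0.496 (permutation p = 0.102, adjusted p = 0.174; rho = 0.510, permutation p = 0.0938; without the same sows 0.543), at -0.043 within the high and 0.817 within the low group, which leaves array hybridisation open too.

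Some probe sets were on in some sows and off in others, with a gap of at least 2.5 and at least 3 sows on each side. There were 9, and 0 of 100 draws of normal values with the same means and SDs gave as many (highest 3). That argues against independent, normally distributed values only. The draws had no floor, whereas GCRMA draws dim values toward one, and the off sows averaged from 2.28 to 3.88. A gap between floor and signal that comes from the processing therefore stays open. Liver RNA may account for ALB and for both probe sets of CYP3A39, a liver cytochrome on in low 1, low 3 and low 4, since 88.6% of the 35 liver markers dim in the median sow and above 4 in some sow had their 2 highest levels in low 1 and low 4. Whether it entered when tissue was taken or during handling, or whether the ovary itself expressed these genes, was not tested. A sequence variant under the probes could not be tested, as 0 other bright probe sets of the same genes were there to compare.

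The remaining probe sets of that kind were not on in the same set of sows as albumin. FCN2, a ficolin of innate immunity, was on in 6 sows, 3 of each group, with a gap of 2.86 to the others, where it averaged 2.56. A probe set with no symbol was on in high 4, high 5 and high 6 alone, at 7.78 against 3.44. The smallest adjusted p of a Fisher's exact test against the groups was 0.545 over the 9.

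Other splits of the sows were refitted, 100 of the 462 possible. A count of 174 or more probe sets at an unadjusted p under 0.01 was given by 19 of the 100, the real one included, so chance cannot be excluded for that count. The highest other count was 989 and the median 75. Adjusted calls were 0 for the real split, so that all 100 had to give as many or more and the comparison decides nothing. The highest other count was 11, and 4 splits gave any. The split with 989 shows how far the count can move between splits of the same sows, and its cause was not tested.

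The spread was wider among high than among low prolificacy sows, without passing a test. The median log2 ratio of the variances, high over low, was 0.95 (exact permutation p = 0.0606), and it was 0.65 without high 3 and 1.07 without high 6, the lowest and highest with 1 high sow left out.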
